A study of Arabidopsis thaliana with 12 samples.

How the data were processed

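RNA was measured in rosettes of 3-week-old soil-grown Arabidopsis thaliana, in 12 libraries of polyadenylated RNA. There were 4 genotypes with 3 libraries each: Col-0 (called the parent in the labels), ceh1, eds16 and ceh1/eds16, and per the series' design text the 3 libraries are biological replicates. The ceh1 plants carry a mutation in HDS, the gene of the enzyme that uses methyl-erythritol cyclodiphosphate in the plastid. The eds16 plants lack a working ICS1, the gene of the enzyme that makes most salicylic acid under stress.

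The deposited values were a signal per gene and library, in the form of read counts that the authors had divided by 1 size factor per library. The submitters' processing notes name TopHat2, DESeq2 and the genome build TAIR10, and the versions are not given in the sources used here. The table held 33602 genes, of which 4115 had no reads in any library. Within each library every value was a whole multiple of 1 step, so whole reads could be recovered: the share of values that came out whole within 0.01 was 100% in each of the 12 libraries. Before the data were examined the values were taken to be normalized counts and not raw counts, and this held.

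Reads in genes per library, in units of 1 M, were 7.33, 4.99 and 6.64 in Col-0, 18.08, 11.18 and 7.4 in ceh1, 8.9, 6.48 and 8.18 in eds16, and 8.49, 7.15 and 8.7 in ceh1/eds16. Genes of the chloroplast and mitochondrial genomes held 0% of the reads. Libraries with fewer reads give wider errors for genes with few reads, and genes with few reads were filtered out as described next.

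Genes were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a trend of the variance on the mean. All 12 libraries were in 1 model of 4 group means, with 8 residual and 8.69 prior degrees of freedom. Genes with a mean normalized count of at least 10 over the 12 libraries were kept, which left 18289 genes and removed 15313. The pseudocount of 1 understates the fold changes of genes with few reads, and all fold changes in the text are on this scale. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and genes were called at an adjusted p under 0.05.

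There were 5 comparisons: ceh1 with Col-0, ceh1/eds16 with eds16, the difference between these 2 effects (the interaction), eds16 with Col-0, and ceh1/eds16 with ceh1. The first 2 share no library, so their overlap is not produced by a common control. The share of the ceh1 response kept in the eds16 background was the median, over genes called in ceh1 against Col-0, of the log2 fold change in ceh1/eds16 against eds16 divided by that in ceh1 against Col-0. Its standard error was taken by the jackknife over libraries. Its value with no interaction was computed from 10 simulated data sets with equal effects in both backgrounds.

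Genes were named in the text by a rule written before the data were examined. In each comparison it took called genes with a symbol, a mean of at least 100 in the highest group and, except for the interaction, no overlap between the libraries of the 2 groups. Of these it took the 8 largest changes in each direction, or 5 in each direction for the comparisons of eds16 with Col-0 and of ceh1/eds16 with ceh1. It also took ICS1, HDS, PR1, PR2 and PR5, and up to 4 members of each gene list. With 3 libraries against 3, groups do not overlap in 10% of chance arrangements. Genes outside this rule are marked in the text as chosen after their values were seen.

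The 26 pathway lists and 6 marker lists were also written before the data were examined and had 495 members. Of these, 479 had the same symbol in the TAIR10.1 RefSeq annotation, 8 had another spelling and 8 had no symbol, and none was left out. The pathway lists were the MEP pathway, the mevalonate pathway, salicylic acid, pattern-triggered immunity, intracellular immune receptors, cysteine-rich and wall-associated receptor kinases, camalexin and indole glucosinolates, aliphatic glucosinolates, jasmonate, ethylene, endoplasmic reticulum stress, the rapid general stress response, heat shock, oxidative stress, photosynthesis, chlorophyll synthesis, carotenoids, abscisic acid, auxin, cell wall expansion, the cell cycle, flavonoids and anthocyanins, senescence, the circadian clock, iron and phosphate starvation. The marker lists were of trichomes, the stomatal lineage and guard cells, vascular tissue, flowers and bolting, roots and seed storage. Lists were tested with limma camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. Coordinates are from the TAIR10.1 RefSeq annotation, which holds 32835 of the loci in the table, while the submitters' notes name TAIR10.

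Alternatives tried were pseudocounts of 0.5 and 5, no filter and a filter at 50, scaling to equal upper quartile or equal library total, quantile normalization, limma without the trend or with robust variances, only the groups of the comparison, the replicate number as a block, and each library left out in turn. Because whole reads were recovered, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald) were run on them as alternatives. In the order of the 5 comparisons above, edgeR called 9309, 7793, 880, 582 and 2285 genes and DESeq2 called 9121, 7689, 1313, 965 and 2404. One alternative, the removal of each library's trend on exon length and GC content, was chosen after a library had been seen to stand apart, and its properties covered 99.9% of the genes tested. Counts of list members, and of differences along and against the ceh1 effect, with each library left out were also chosen after that library had been seen.

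The test was tried on simulated data with separate sets of 200 genes changed by ceh1, by eds16 and in ceh1/eds16 alone. A list of 30 other genes was raised 1.5-fold by ceh1. In the order of the comparisons above, genes changed 4-fold were called in 100%, 100%, 92.4%, 100% and 97% of cases, and genes changed 2-fold in 82.1%, 89.6%, 35.8%, 76.1% and 76.1%. Genes changed 1.5-fold were called in 20.9%, 47.8%, 6%, 29.9% and 34.3%, and false calls made up 8.1%, 6%, 11.9%, 8.1% and 5.6%. The interaction was thus the comparison in which most simulated 2-fold differences went uncalled. Far fewer genes changed in the simulation than in ceh1 against Col-0, where 50.2% of the genes tested were called. The cutoff for a call depends on that number, so these rates are not those of the real comparisons. Sequence reads, metabolite levels and hormone levels were not analysed here.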

Results

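Transcript levels were compared in rosettes of Col-0, ceh1, eds16 and ceh1/eds16 plants, with 3 biological replicates per genotype and 18289 genes tested. Libraries held 4.99 M to 18.08 M reads in genes. Gene values below are normalized counts as mean ± SD of n = 3 libraries, and log2 fold changes and adjusted p are from limma on log2(normalized count + 1), a scale that understates the change of genes with few reads.

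ICS1 (chromosome 1, 28070295 to 28074177, TAIR10.1, protein-coding), the isochorismate synthase gene disrupted in eds16, stood at 245 ± 27.6 in Col-0, 666 ± 31.2 in ceh1, 15.2 ± 4.47 in eds16 and 21 ± 7.06 in ceh1/eds16. Its libraries read 235, 277 and 224 in Col-0, 631, 677 and 690 in ceh1, 19.2, 16 and 10.4 in eds16, and 14.2 to 28.3 in ceh1/eds16. The transcript was thus 15.6-fold lower in eds16 than in Col-0 (adjusted p = 9.28e-08, limma) and 31.4-fold lower in ceh1/eds16 than in ceh1 (adjusted p = 6.19e-10), in all libraries. HDS (chromosome 5, 24358885 to 24363485, protein-coding), which carries the ceh1 point mutation and encodes the plastid enzyme that consumes methyl-erythritol cyclodiphosphate, stood at 3765 ± 159, 1589 ± 240, 3683 ± 287 and 2338 ± 274 in the same order of genotypes. Its libraries read 3840, 3874 and 3582 in Col-0, 1565, 1362 and 1840 in ceh1, 3955, 3383 and 3711 in eds16, and 2238, 2649 and 2128 in ceh1/eds16. A point mutation need not change the amount of transcript, so these HDS values do not check the ceh1 labels, but the transcript was 2.39-fold lower in ceh1 than in Col-0 (adjusted p = 5.83e-07, limma).

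The largest spread among the libraries, a first component with 69.9% of the variance, separated the ceh1 and ceh1/eds16 libraries from the Col-0 and eds16 libraries. A second component, with 8.6%, separated the libraries with and without a working ICS1. Component 3, with 6.8%, spread the libraries of ceh1 and of ceh1/eds16 within their groups. It also separated Col-0 (scores 6.6 to 21.8) from eds16 (-23.3 to -11.4). Replicate 3 of ceh1/eds16 stood apart from its group. Its squared differences in read counts from the other 2 replicates were 23.3 and 23.2 times those of read sampling. All other pairs within a group had 2.4 to 8.9 times, and this ratio also grows with the number of reads.

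**Figure D1:**
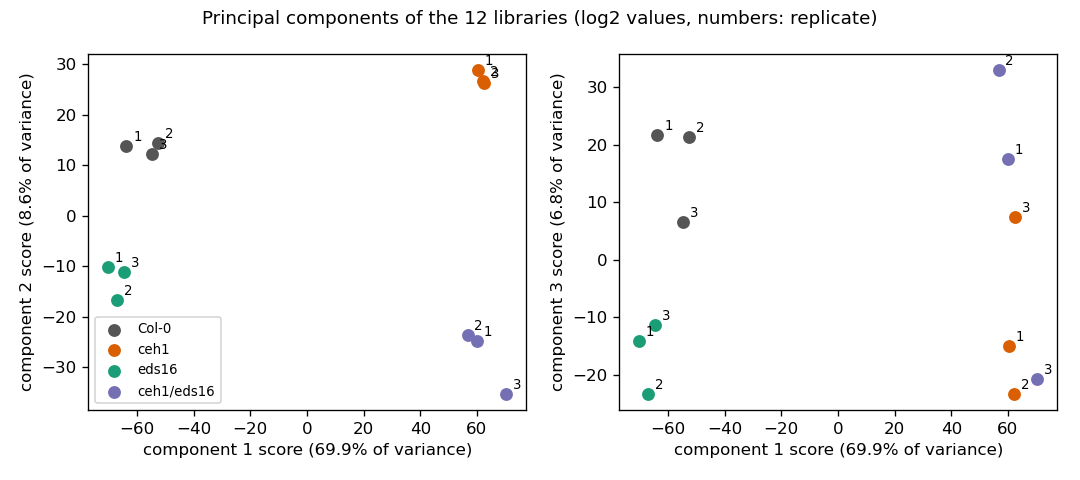
Position of the 12 libraries on the first 3 principal components of log2(normalized count + 1), with each axis giving its percent of the variance (69.9%, 8.6% and 6.8%). Each dot is a library coloured by genotype; the first axis separates the genotypes with ceh1 from the others.

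In ceh1 the salicylic acid pathway was higher than in Col-0, and the pathogenesis-related gene PR1 (chromosome 2, 6241640 to 6242541, protein-coding) rose 24.4-fold, from 311 ± 117 to 7388 ± 1949 (adjusted p = 1.68e-09, limma). PR2, a glucanase gene (chromosome 3, 21188397 to 21189967), rose from 635 ± 172 to 6229 ± 900 (adjusted p = 1.71e-10). PR5, a thaumatin-like protein gene (chromosome 1, 28177670 to 28179022), rose from 314 ± 93.7 to 1072 ± 122 (adjusted p = 8.65e-07). The transcription factor gene WRKY38 rose from 13.7 ± 4.19 to 526 ± 42.7, WRKY51 from 5.12 ± 2.91 to 345 ± 40.4, and NIMIN1, whose product binds the salicylic acid receptor NPR1, from 8.88 ± 4.66 to 168 ± 34.2. Of 33 measured members of the salicylic acid list 30 rose and 1, ICS2, fell (list adjusted p = 5.5e-14, limma camera), and ICS1 itself rose by 1.44 ± 0.23 (SE) on the log2 scale. In all, 9183 genes were called, 4617 higher and 4566 lower, of which 1821 and 1289 changed at least 2-fold, and 10240 genes had an unadjusted p under 0.05.

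Other immune genes rose with them in ceh1. CRK7 went from 50.3 ± 10.5 to 556 ± 61.2 and WAKL10 from 10.3 ± 8.7 to 142 ± 31.2. Of 14 cysteine-rich and wall-associated receptor kinases 13 rose (list adjusted p = 7.91e-09, limma camera, or adjusted p = 0.12 with an estimated correlation). FRK1, a receptor kinase gene induced by microbial patterns, went from 18.4 ± 7.39 to 198 ± 21.9. Among 20 genes of pattern-triggered immunity 13 rose and 2 fell (list adjusted p = 6.59e-05, or adjusted p = 0.137 with an estimated correlation). PAD3, the gene of the last step of camalexin synthesis, went from 34.6 ± 8.34 to 551 ± 93.8. For camalexin and indole glucosinolate synthesis 7 of 11 genes rose and 1, MYB34, fell (list adjusted p = 0.0043, or adjusted p = 0.092 with an estimated correlation). Intracellular immune receptors did not pass as a list (adjusted p = 0.0613), with 6 of 13 higher, among them ADR1, and 1 lower, or 2 lower without ceh1 replicate 3 or ceh1/eds16 replicate 3. Pattern-triggered immunity had 1 lower in all leave-outs of 1 library except those of ceh1 replicate 2, eds16 replicate 2 and ceh1/eds16 replicate 3.

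Genes of the endoplasmic reticulum stress response rose in ceh1 in 23 of 25 members with none lower (list adjusted p = 1.25e-15, limma camera). BIP3 (chromosome 1, 2929217 to 2931850), a chaperone gene induced by unfolded proteins, rose 35.9-fold, from 56.2 ± 8.85 to 2036 ± 95.6, and the transcription factor gene NAC103 from 15.3 ± 5.78 to 313 ± 33.6. ZAT12 went from 11.7 ± 3.38 to 320 ± 91.8 and WRKY40 from 19.3 ± 2.35 to 399 ± 150. In the rapid general stress response, which holds both, 15 of 22 genes rose and 2 fell (list adjusted p = 1.03e-07, or adjusted p = 0.16 with an estimated correlation). The alternative oxidase gene AOX1D rose from 3.27 ± 0.786 to 94.6 ± 11 and the catalase gene CAT2 fell from 5096 ± 876 to 1725 ± 81.7. The oxidative stress list of 18 had 11 higher and 2 lower (list adjusted p = 0.00183, or adjusted p = 0.112 with an estimated correlation). Heat shock genes did not move as a list, with 2 of 9 higher and 2 lower (adjusted p = 0.943). The higher ones were 1 without Col-0 replicate 2 or 3 or ceh1 replicate 1 or 2, and the lower ones 1 without Col-0 replicate 1 or 2 or ceh1 replicate 1 or 2. Rapid stress genes had 1 lower without Col-0 replicate 2 or ceh1 replicate 2.

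Jasmonate and ethylene genes were also higher in ceh1. For jasmonate 22 of 32 rose and 3 fell (list adjusted p = 0.000126, limma camera, or adjusted p = 0.281 with an estimated correlation). TAT3, a tyrosine aminotransferase gene, went from 82.9 ± 20.2 to 792 ± 84.4, while the methyltransferase gene JMT fell from 21.2 ± 9.34 to 4.67 ± 2.01. The defensin gene PDF1.2A (chromosome 5, 17906968 to 17907638), a marker of joint jasmonate and ethylene signalling, read 17.8 ± 2.38 in Col-0 and 13.5 ± 4.46 in ceh1 (adjusted p = 0.289). ERF104 went from 46.1 ± 11.4 to 384 ± 60.1. For ethylene 9 of 15 rose and 3 fell (list adjusted p = 0.0266, or adjusted p = 0.162 with an estimated correlation). The ethylene list failed at an adjusted p of 0.0564 without ceh1 replicate 3. SAG13 rose from 112 ± 43.7 to 2541 ± 19.2 and SEN1 fell from 431 ± 144 to 132 ± 48.9. Senescence genes had 8 of 12 higher and 1 lower (list adjusted p = 0.00381, or adjusted p = 0.12 with an estimated correlation).

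Nuclear genes of plastid functions fell in ceh1. All 12 genes of chlorophyll synthesis were lower (list adjusted p = 1.59e-07, limma camera). PORA, a protochlorophyllide reductase gene, was 11.6-fold lower at 56.9 ± 4.85 against 670 ± 35.6, and CHLH stood at 5558 ± 696 against 22890 ± 4995. In photosynthesis 38 of 40 genes fell, such as RCA, the Rubisco activase gene, from 68920 ± 5267 to 25940 ± 1671 (list adjusted p = 1.21e-14, or adjusted p = 0.175 with an estimated correlation). Carotenoid genes had 10 of 12 lower, CCD4 among them at 1463 ± 32.1 against 4054 ± 637 (list adjusted p = 1.84e-05, or adjusted p = 0.107 with an estimated correlation). The MEP pathway, in which HDS acts, had 5 of 7 genes lower and none higher (list adjusted p = 0.0042, or adjusted p = 0.12 with an estimated correlation). Its first gene, DXS, went from 7972 ± 626 to 3139 ± 336. The mevalonate pathway of the cytosol had 1 of 12 higher and 5 lower, with HMG1 falling from 3955 ± 228 to 1515 ± 117 (list adjusted p = 0.0838).

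IAA29 fell from 278 ± 81.4 to 34.7 ± 2.48 and GH3.2 rose from 13.2 ± 0.935 to 69.8 ± 4.08. Auxin genes had 10 of 18 lower and 4 higher (list adjusted p = 0.0171, limma camera, or adjusted p = 0.12 with an estimated correlation). Of 7 cell wall expansion genes 5 fell and 1 rose, EXPA11 going from 303 ± 3.42 to 79.7 ± 4.1 (list adjusted p = 0.0122, or adjusted p = 0.162 with an estimated correlation). All 7 vascular markers were lower, CESA4 and CESA8 of secondary wall cellulose among them (list adjusted p = 0.00093, or adjusted p = 0.16 with an estimated correlation). Aliphatic glucosinolate synthesis had 12 of 15 genes lower and 1 higher (2 higher without Col-0 replicate 1), and its regulator MYB29 fell from 523 ± 144 to 162 ± 21.3 (list adjusted p = 0.000853, or adjusted p = 0.281 with an estimated correlation). Large falls outside the lists included those of the wax gene CER4, from 178 ± 38.1 to 18.4 ± 4.62, and of DOT3, from 209 ± 12.4 to 21.7 ± 2.33. The largest fall among the named genes was that of CSLA01, at -4.566 to -3.777 (log2) when each library was left out.

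Lists with mixed members in ceh1 were the circadian clock, with 8 of 14 higher and 3 lower (adjusted p = 0.0952, limma camera), and abscisic acid, with 4 of 18 higher and 7 lower (0.259). Flavonoid genes had 1 of 14 higher and 6 lower (0.187) and the cell cycle 6 of 10 higher and 1 lower (0.0838). Iron had 3 of 9 higher and 2 lower (0.943), phosphate starvation 3 of 5 higher and 1 lower (0.0981), and floral markers 2 of 11 higher and 7 lower (0.0898). Trichome markers (1 of 4 higher, 1 lower, 0.954) and guard cell markers (1 of 9 higher, 2 lower, 0.893) did not pass; of these the potassium channel gene KAT1 fell from 298 ± 28 to 84.9 ± 11.3. Abscisic acid had 2 higher without Col-0 replicate 1, and iron and floral markers 1 higher each without Col-0 replicate 2. Guard cell markers had 2 higher without Col-0 replicate 2, ceh1 replicate 3 or ceh1/eds16 replicate 1 or 3, and 1 lower without any 1 of Col-0 replicates 1, 2 and 3 and ceh1 replicates 1 and 2. Counts adjusted over the list alone were the same except for pattern-triggered immunity (14 higher), endoplasmic reticulum stress (24 higher), carotenoids (11 lower) and abscisic acid (8 lower). Root and seed storage markers were not tested, with 1 of 8 and 0 of 7 members passing the filter. The root marker was PYK10, at 153 ± 37.3 in Col-0 and 808 ± 125 in ceh1.

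**Figure D2:**
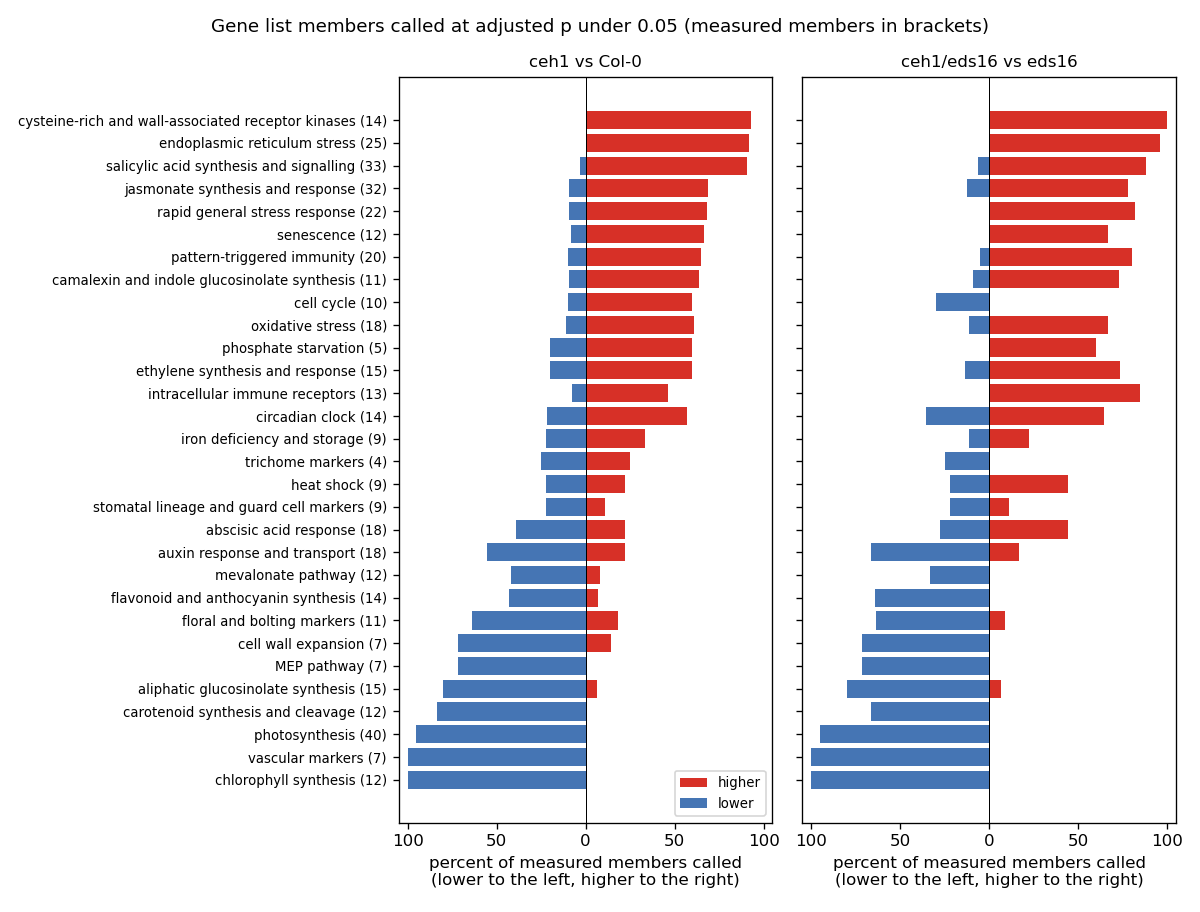
Percent of the measured members of each of the 30 tested gene lists called higher or lower in ceh1 against Col-0 and in ceh1/eds16 against eds16; each bar is a list in a comparison. Endoplasmic reticulum stress and salicylic acid genes are mostly higher in both, photosynthesis and chlorophyll genes lower in both.

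With ICS1 lost, ceh1 still moved most of the same genes. In ceh1/eds16 against eds16, PR2 rose 35.2-fold, from 152 ± 10.6 to 5397 ± 540 (adjusted p = 1.18e-12, limma), and PR5 from 77.6 ± 4.46 to 1021 ± 238 (adjusted p = 1.42e-10), to levels near those of ceh1. BIP3 rose 83.6-fold, from 19.1 ± 4.23 to 1656 ± 96.2, and FMO1, a gene of systemic acquired resistance, 79.9-fold, from 5.57 ± 2.82 to 493 ± 79.3. PR1 went only from 43.3 ± 8.86 to 85.7 ± 24, a rise of 0.95 ± 0.28 (SE, log2, adjusted p = 0.0102) that was 0.78 with an adjusted p of 0.053 without ceh1/eds16 replicate 1. ICS1 showed 0.43 ± 0.23 (adjusted p = 0.145), and HDS fell by 0.66 ± 0.13 (adjusted p = 0.000437). In all, 7736 genes were called, 4036 higher and 3700 lower, of which 1836 and 1370 changed at least 2-fold.

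By list, in ceh1/eds16 against eds16, 29 of 33 salicylic acid genes rose and 2 fell (adjusted p = 3.12e-13, limma camera), and 24 of 25 endoplasmic reticulum stress genes rose (adjusted p = 1.5e-14). All 12 chlorophyll genes fell (adjusted p = 9.54e-08), and 8 of 11 camalexin genes rose with 1 lower (adjusted p = 0.000238). These 4 held with an estimated correlation, as did the first 3 in ceh1 against Col-0. PAD3 rose from 41.5 ± 8.32 to 1177 ± 96.9, and PORA fell from 365 ± 60.7 to 39.5 ± 9. Receptor kinases rose in 14 of 14 (adjusted p = 1.19e-11, or adjusted p = 0.0601 with an estimated correlation) and pattern-triggered immunity in 16 with 1 lower (3.71e-08, or adjusted p = 0.0593 with an estimated correlation). Intracellular receptors rose in 11 with none lower (3.87e-05, or adjusted p = 0.122 with an estimated correlation). Rapid stress genes had 18 higher and none lower (3.98e-12, or adjusted p = 0.0604 with an estimated correlation), and oxidative stress genes 12 higher and 2 lower (9.33e-05, or adjusted p = 0.0513 with an estimated correlation). The lower ones were 1 in all leave-outs of 1 library except those of ceh1 replicate 3, eds16 replicates 1 and 2 and ceh1/eds16 replicate 3. Jasmonate had 25 higher and 4 lower (9.54e-08, or adjusted p = 0.137 with an estimated correlation). Ethylene had 11 and 2 (0.000461, or adjusted p = 0.0593 with an estimated correlation), and senescence 8 and 0 (0.00066, or adjusted p = 0.0601 with an estimated correlation).

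Falling lists in ceh1/eds16 against eds16 included photosynthesis, 38 of 40 (adjusted p = 5.21e-14, limma camera, or adjusted p = 0.159 with an estimated correlation). The antenna gene LHCB2.3, outside the list, went from 7578 ± 758 to 552 ± 63.2. Carotenoids had 8 lower (0.00031, or adjusted p = 0.0752 with an estimated correlation). The MEP pathway had 5 (0.00193, or adjusted p = 0.0601 with an estimated correlation) and mevalonate 4 (0.0191, or adjusted p = 0.0644 with an estimated correlation). Aliphatic glucosinolates had 12 lower and 1 higher (2.89e-05, or adjusted p = 0.164 with an estimated correlation). Auxin had 12 and 3 (0.00175, or adjusted p = 0.0593 with an estimated correlation), and cell wall expansion 5 and 0 (0.000367, or adjusted p = 0.0604 with an estimated correlation). Flavonoids had 9 lower (0.000147, or adjusted p = 0.0593 with an estimated correlation). Vascular markers had 7 (0.000193, or adjusted p = 0.0814 with an estimated correlation), and floral markers 7 lower and 1 higher (0.00554, or adjusted p = 0.189 with an estimated correlation). Heat shock (4 higher, 2 lower), abscisic acid (8 and 5), cell cycle (0 and 3), clock (9 and 5), iron (2 and 1), phosphate (3 and 0), trichome (0 and 1) and guard cell lists (1 and 2) did not pass. Iron had 1 higher without eds16 replicate 1 or 3 or ceh1/eds16 replicate 1 or 2, and trichome markers 2 lower without ceh1/eds16 replicate 3. Guard cell markers had 2 higher without ceh1/eds16 replicate 1 and 1 lower without eds16 replicate 1 or 2. Adjusted over the list alone the counts differed for the MEP pathway (6 lower), carotenoids (9 lower), abscisic acid (9 higher) and floral markers (8 lower).

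Of the 4617 genes higher in ceh1, 2977 (64.5%) were also higher in ceh1/eds16 against eds16, where 1018.9 would be shared by independent calls, and 29 were lower. Of the 4566 lower genes, 2663 (58.3%) were also lower, against 923.7, and 36 were higher. In simulated data with equal effects in both backgrounds, 80.8% of the genes called in ceh1 were also called in the eds16 background, more than either share. The median share of the ceh1 effect kept in the eds16 background was 0.832 ± 0.11 (jackknife SE) for higher genes and 0.694 ± 0.118 for lower genes. Simulated equal effects gave 0.928 and 0.933. The simulation took the measured fold changes as true and held neither a deviating library nor a gene length trend. Gaps between the data and the simulation are thus not by themselves a loss of response. Across 18289 genes the 2 effects correlated at 0.853 (Spearman 0.77), and genes are not independent replicates. Clock genes moved the same way in both comparisons as well, with CCA1 and PRR9 lower and FKF1 and GRP7 higher (values below). No label gives the hour of harvest, so a part of time of day in the shared changes cannot be told apart from genotype. Without ceh1/eds16 replicate 3 the kept shares were 0.755 and 0.611, and the shared genes 57.3% and 52%.

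**Figure D3:**
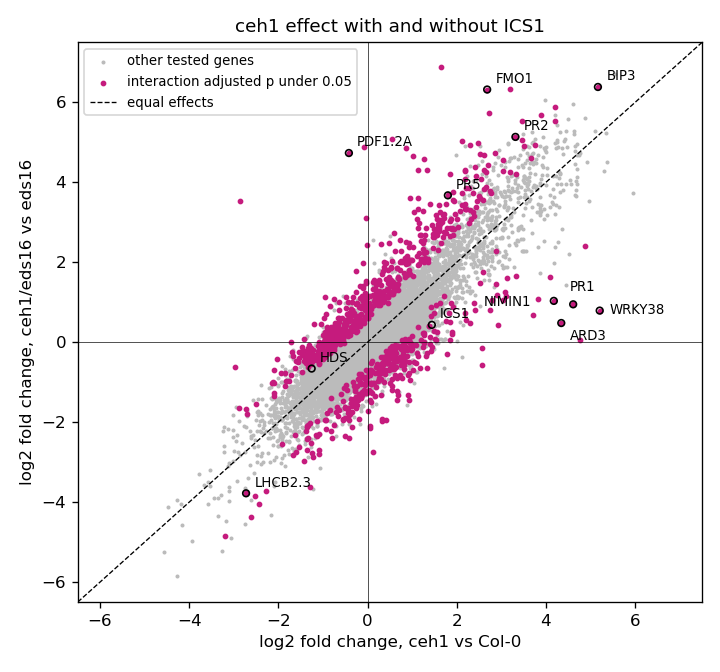
Log2 fold change of each gene in ceh1 against Col-0 (x axis) and in ceh1/eds16 against eds16 (y axis), each dot a gene and the dashed line equal effects. Coloured genes differ between the backgrounds; PR1, WRKY38, ARD3 and NIMIN1 lie below the line, FMO1 and PDF1.2A above it.

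A group of genes rose in ceh1 and hardly in ceh1/eds16. Most were named as the largest negative values among genes called in the test of the difference between the 2 ceh1 effects. Their calls in that test are thus no separate evidence. The difference was -3.66 ± 0.39 (SE, log2) for PR1 (adjusted p = 6.2e-05, limma) and -4.42 ± 0.37 for WRKY38 (adjusted p = 7.07e-06). It was -3.86 ± 0.35 for the methionine salvage gene ARD3 (adjusted p = 1.21e-05) and -3.14 ± 0.48 for NIMIN1 (adjusted p = 0.00145). ARD3 read 20.3 ± 4.06, 430 ± 71.6, 13.8 ± 3.89 and 19.3 ± 3.72 in Col-0, ceh1, eds16 and ceh1/eds16, and NIMIN1 reached 15.9 ± 5.73 in ceh1/eds16. PCC1, a defence gene under clock control, read 495 ± 46.8, 1715 ± 281, 302 ± 72.1 and 254 ± 89.9, with a difference of -2.07 ± 0.31. PCR1, a plasma membrane cadmium resistance gene, rose in both backgrounds but less in ceh1/eds16 (222 ± 50.6 against 3480 ± 628 in ceh1, difference -1.68 ± 0.31).

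A second group rose further in the absence of ICS1. PR2 and PR5 had positive differences of 1.82 ± 0.23 (adjusted p = 0.00025, limma) and 1.87 ± 0.27 (adjusted p = 0.000785), since they started lower in eds16 and ended at similar levels. FMO1 (difference 3.64 ± 0.45, adjusted p = 0.000246) reached 61.6 ± 4.65 in ceh1 and 493 ± 79.3 in ceh1/eds16. The defensin gene PDF1.2A read 46.1 ± 12.1 in eds16 and 1343 ± 724 in ceh1/eds16 (difference 5.15 ± 0.45, adjusted p = 9.49e-06). Its near copies PDF1.2b, PDF1.2c and PDF1.3 had differences of 4.53, 4.96 and 5.25, and their separate values are uncertain because the sequences of the copies are close to each other. Summed over the 4 copies the libraries read 29.7, 37.5 and 27 in Col-0, 37.9, 35.8 and 34.9 in ceh1, 86.4, 87.8 and 73.6 in eds16, and 2724, 1820 and 5614 in ceh1/eds16. The acyltransferase gene AACT1 (AT5G61160) fell in ceh1, from 16.4 ± 5.9 to 1.32 ± 0.326, and rose in ceh1/eds16, from 12.9 ± 11.4 to 128 ± 9.74. Genes of salicylic acid synthesis chosen after their values were seen were in this group. EDS5, the transporter gene, stood at 224 ± 35.7 in ceh1 and 470 ± 124 in ceh1/eds16 (difference 1.60, adjusted p = 0.0097) and PBS3 at 518 ± 27.1 and 1101 ± 143 (adjusted p of the difference 0.00195). ORA59, a regulator of PDF1.2 also chosen after its values were seen, read 40.4 ± 5.8 and 195 ± 68.9 (difference 2.98, adjusted p = 0.0028).

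**Figure D4:**
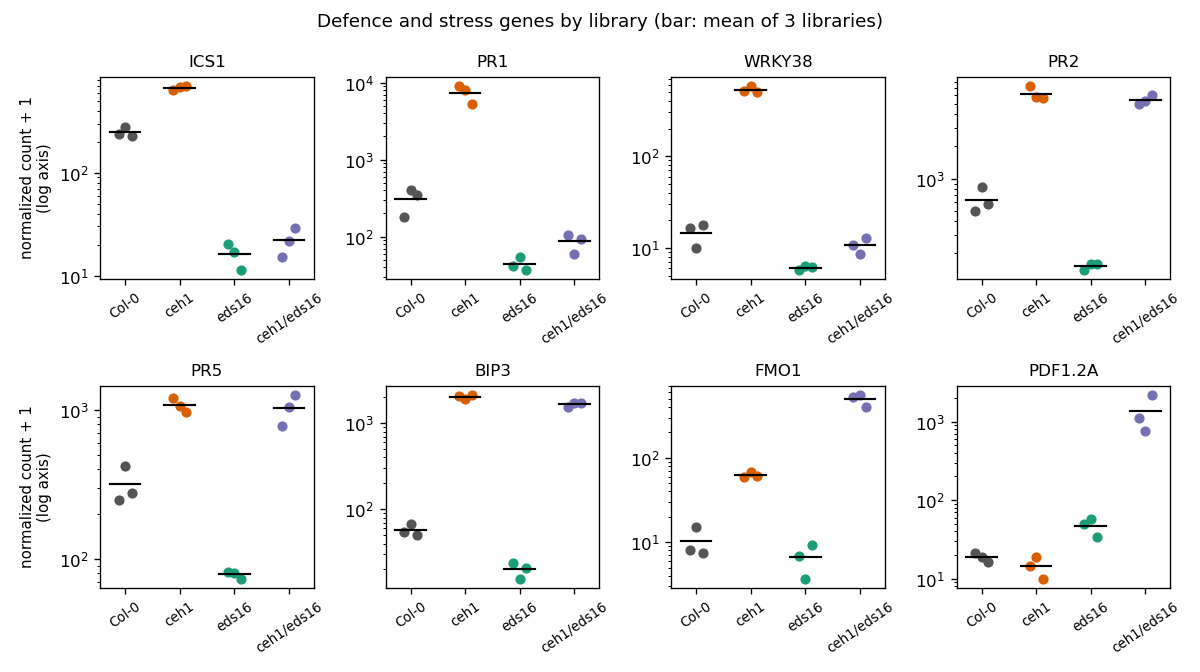
Normalized count + 1 (log axis) of ICS1, PR1, WRKY38, PR2, PR5, BIP3, FMO1 and PDF1.2A in the 4 genotypes; each dot is a library and each bar the mean of 3. PR1 and WRKY38 are high in ceh1 alone, PR2, PR5 and BIP3 in both genotypes with ceh1, and PDF1.2A in ceh1/eds16 alone.

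In all, 891 genes had a ceh1 effect that differed between the backgrounds, 564 in the positive and 327 in the negative direction, and 665 of them were called in ceh1 against Col-0. The other 226 were called only in the eds16 background, 122 higher and 104 lower. Among the genes higher in ceh1 the difference was called against the ceh1 effect in 164 and along it in 209, and among the lower genes in 233 and 59. The balance for higher genes turned round without ceh1/eds16 replicate 3, to 789 against and 365 along, and the lower genes then had 987 and 166. Over the other 11 libraries left out in turn the higher genes had 41 to 194 against and 98 to 217 along, and the lower genes 84 to 312 and 25 to 66. The total count was unsteady as well. Leaving out 1 library gave 347 to 3012, with 3012 without ceh1/eds16 replicate 3, 347 without ceh1 replicate 1, and 354 without ceh1 replicate 2. It was 413 and 469 without eds16 replicates 1 and 2, 585 and 431 without Col-0 replicates 1 and 2, and 499 without ceh1/eds16 replicate 2. Without ceh1/eds16 replicate 3 all 891 genes were called again in the same direction.

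Lists with a positive difference were intracellular receptors, 3 of 13 positive and none negative (8 adjusted over the list alone, list adjusted p = 0.000119, limma camera, or adjusted p = 0.249 with an estimated correlation). Pattern-triggered immunity had 6 of 20 (9 adjusted over the list alone, 0.000683, or adjusted p = 0.249 with an estimated correlation). Rapid stress genes had 4 positive (9 and 1 negative adjusted over the list alone, 0.000119, or adjusted p = 0.363 with an estimated correlation). Receptor kinases had 2 (5 adjusted over the list alone, 0.000434, or adjusted p = 0.363 with an estimated correlation). Camalexin had 2 (5 adjusted over the list alone, 0.00426, or adjusted p = 0.184 with an estimated correlation). Jasmonate had 5 (5 and 2 negative adjusted over the list alone, 0.0149, or adjusted p = 0.588 with an estimated correlation). Ethylene had 3 (4 adjusted over the list alone, 0.00621, or adjusted p = 0.197 with an estimated correlation) and oxidative stress 4 (0.021, or adjusted p = 0.249 with an estimated correlation). A positive difference is not always a higher level in ceh1/eds16 than in ceh1. Receptor kinases had 11 of 14 lower in eds16 than in Col-0, and 7 lower and 0 higher in ceh1/eds16 than in ceh1. Pattern-triggered immunity had 6 lower in eds16 than in Col-0, and 4 lower and 3 higher in ceh1/eds16 than in ceh1. The other positive lists had more higher than lower genes in ceh1/eds16 than in ceh1. Negative lists were endoplasmic reticulum stress, 4 negative and 1, BIP3, positive (6 and 1 adjusted over the list alone, 0.0149, or adjusted p = 0.184 with an estimated correlation). Others were the cell cycle with 2 (7 adjusted over the list alone, 5.47e-05, or adjusted p = 0.184 with an estimated correlation) and flavonoids with 5, among them PAP1 (0.000473, or adjusted p = 0.184 with an estimated correlation). The salicylic acid list was split, 9 positive and 4 negative (11 and 6 adjusted over the list alone, adjusted p = 0.584). The jasmonate call was lost without eds16 replicate 3 (adjusted p = 0.235) and the oxidative stress call without ceh1/eds16 replicate 3 (adjusted p = 0.156).

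The counts of these lists were unsteady when 1 library was left out, and those of endoplasmic reticulum stress and the cell cycle moved with most of the libraries. Without ceh1/eds16 replicate 3 the positive genes were 10 of the intracellular receptors, 6 of the receptor kinases, 5 each of camalexin and ethylene and 4 of abscisic acid. The negative genes were then 7 of endoplasmic reticulum stress, 7 of salicylic acid and 6 of the cell cycle. Endoplasmic reticulum stress had 0 negative genes without Col-0 replicate 1 or 2, ceh1 replicate 1 or 2, eds16 replicate 1 or 2, or ceh1/eds16 replicate 1 or 2. It had 1 without Col-0 replicate 3 and 2 without ceh1 replicate 3. Intracellular receptors had 1 positive gene without Col-0 replicate 2, ceh1 replicate 1 or 2, eds16 replicate 1 or ceh1/eds16 replicate 2. Receptor kinases had 1 without Col-0 replicate 1 or 2, ceh1 replicate 1 or 2, eds16 replicate 1, or ceh1/eds16 replicate 1 or 2. Ethylene had 1 without ceh1 replicate 1 or 2 or eds16 replicate 1, camalexin 4 without ceh1 replicate 3, and oxidative stress 2 without Col-0 replicate 2, ceh1 replicate 1 or eds16 replicate 1 or 2. Rapid stress genes had 7 positive without ceh1 replicate 3. They had 2 without Col-0 replicate 2 or 3, ceh1 replicate 1 or 2, eds16 replicate 1, or ceh1/eds16 replicate 1 or 2. Flavonoids had 1 negative gene without Col-0 replicate 2 or eds16 replicate 1 or 2, 2 without ceh1 replicate 1 or 2, and 3 without ceh1/eds16 replicate 1 or 2. The cell cycle had 0 without ceh1 replicate 1, 4 without eds16 replicate 3, and 1 without Col-0 replicate 1 or 2, ceh1 replicate 2 or 3, eds16 replicate 1 or 2, or ceh1/eds16 replicate 1 or 2.

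Clock genes moved in ceh1 and further in ceh1/eds16. The morning gene CCA1 fell from 746 ± 21.2 in Col-0 to 308 ± 1.99 in ceh1 and from 610 ± 41.1 in eds16 to 113 ± 48.8 in ceh1/eds16 (difference -1.26 ± 0.33, adjusted p = 0.0368, limma). PRR9, another morning gene, went from 664 ± 35.7 to 246 ± 18.5 and from 622 ± 16.3 to 81.2 ± 29.2 (difference -1.55 ± 0.25, adjusted p = 0.0021). The afternoon gene FKF1 rose from 41.1 ± 9.92 to 281 ± 55.2 and from 60 ± 11.8 to 684 ± 65.1 (difference 0.75 ± 0.27, adjusted p = 0.118). GRP7 rose from 2368 ± 203 to 10740 ± 860 and from 2019 ± 240 to 24320 ± 12880 (difference 1.29 ± 0.34, adjusted p = 0.0383). COR27, an evening-phased gene, reached 70.3 ± 26.4 in ceh1 and 788 ± 158 in ceh1/eds16, and TOC1, chosen after its values were seen, 592 ± 81.7 and 1617 ± 107. The clock list as a whole did not pass in the difference (5 positive and 3 negative, or 7 and 3 adjusted over the list alone, adjusted p = 0.205), as its members moved in both directions. It had 3 positive without Col-0 replicate 2 or 3, ceh1 replicate 1 or 2, or eds16 replicate 1. The time of harvest of the groups is not among the facts used here.

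**Figure D5:**
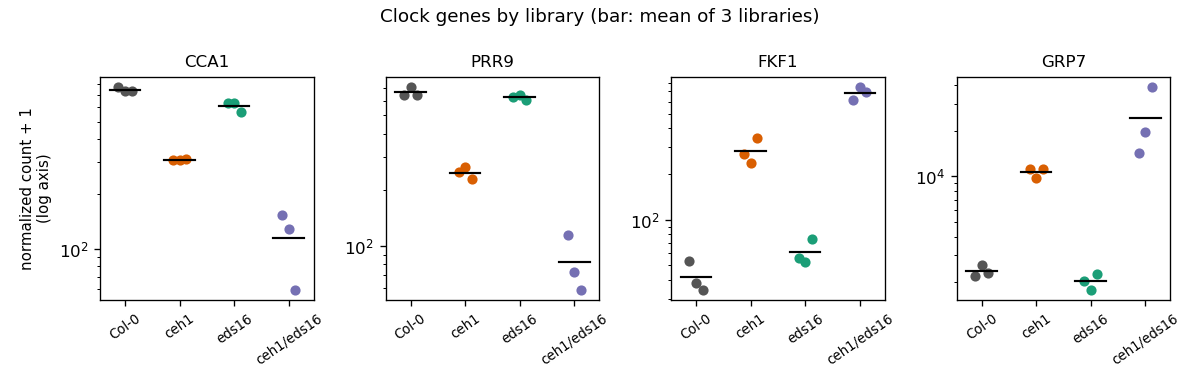
Normalized count + 1 (log axis) of the clock genes CCA1, PRR9, FKF1 and GRP7 in the 4 genotypes; each dot is a library and each bar the mean of 3. CCA1 and PRR9 are lowest, and FKF1 and GRP7 highest, in ceh1/eds16.

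Loss of ICS1 alone lowered the basal level of salicylic acid genes. Between Col-0 and eds16, PR1 fell from 311 ± 117 to 43.3 ± 8.86 (6.74-fold lower, adjusted p = 2.24e-05, limma), PR2 from 635 ± 172 to 152 ± 10.6 (adjusted p = 2.16e-06) and PR5 from 314 ± 93.7 to 77.6 ± 4.46 (adjusted p = 1.52e-05). The glucanase gene BG3 fell from 52.1 ± 25.8 to 2.41 ± 1.29, and the receptor-like protein gene RLP23 from 233 ± 56.4 to 44.5 ± 14.8. Rises were fewer: VSP2, a storage protein gene induced by jasmonate, went from 474 ± 131 to 2114 ± 1282 (adjusted p = 0.00254), IGMT5, of indole glucosinolate methylation, from 35.6 ± 7.11 to 107 ± 35.3, and SCPL9 from 40 ± 4.74 to 120 ± 20.8. HDS showed -0.03 ± 0.13 (log2, adjusted p = 0.908). Of 841 genes called, 299 were higher and 542 lower, with 88 and 163 changed at least 2-fold.

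By list, 17 of 33 salicylic acid genes fell in eds16 and none rose (22 adjusted over the list alone, list adjusted p = 3.98e-18, limma camera), and this held with an estimated correlation. ICS1, the gene disrupted in eds16, is a member of this list and is counted among the lower genes and in the list test. Receptor kinases fell in 11 of 14 (12 adjusted over the list alone, 3.55e-13, or adjusted p = 0.145 with an estimated correlation). Pattern-triggered immunity fell in 6 of 20 (12 adjusted over the list alone, 5.39e-07, or adjusted p = 0.145 with an estimated correlation). Intracellular receptors fell in 4 of 13 (6 adjusted over the list alone, 2.73e-05, or adjusted p = 0.257 with an estimated correlation). Endoplasmic reticulum stress genes had 2 lower, BIP3 among them (4 adjusted over the list alone, 0.00572, or adjusted p = 0.145 with an estimated correlation). Higher lists were jasmonate, 6 higher and 1 lower (9 and 1 adjusted over the list alone, 0.00089, or adjusted p = 0.484 with an estimated correlation), and flavonoids, 4 higher (0.00254, or adjusted p = 0.217 with an estimated correlation). The cell cycle had 2 higher (5 adjusted over the list alone, 0.00232, or adjusted p = 0.301 with an estimated correlation), and failed at 0.0666 without Col-0 replicate 2. Floral markers had 1 higher (0.000418, or adjusted p = 0.257 with an estimated correlation). Photosynthesis had none called either way, and the clock none (1 lower adjusted over the list alone). Without ceh1/eds16 replicate 3 photosynthesis had 3 higher and 1 lower, and the clock 1 and 1. Leaving out 1 library gave 238 to 1780 called genes: 422 and 238 without Col-0 replicates 1 and 2, 288 and 308 without eds16 replicates 1 and 2, 553 without ceh1 replicate 1 and 1780 without ceh1/eds16 replicate 3. Salicylic acid genes then ran from 10 lower, without Col-0 replicate 2 or eds16 replicate 1, to 20 without ceh1/eds16 replicate 3, with 11 without eds16 replicate 2. The cell cycle had 0 higher without Col-0 replicate 1 or 2 or eds16 replicate 1 or 2 and 1 without ceh1 replicate 1 or eds16 replicate 3. Pattern-triggered immunity had 3 lower without Col-0 replicate 2 or eds16 replicate 1. Intracellular receptors had 1 lower without Col-0 replicate 2 and 2 without Col-0 replicate 1 or eds16 replicate 1 or 2. Endoplasmic reticulum stress had 1 lower without Col-0 replicate 2 and 5 without ceh1/eds16 replicate 3, and floral markers 2 higher without ceh1 replicate 3. Jasmonate had 3 higher without any 1 of Col-0 replicates 1, 2 and 3 and eds16 replicates 1 and 2.

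Between ceh1 and ceh1/eds16, PR1 fell 85.4-fold, from 7388 ± 1949 to 85.7 ± 24 (adjusted p = 3.3e-10, limma). PR2 stood at 6229 ± 900 and 5397 ± 540 (adjusted p = 0.502) and PR5 at 1072 ± 122 and 1021 ± 238 (adjusted p = 0.827). WRKY38 fell 49.9-fold, and PCR1 fell from 3480 ± 628 to 222 ± 50.6. PDF1.2A rose 87.3-fold (adjusted p = 1.3e-09), and AACT1 (AT5G61160) rose from 1.32 ± 0.326 to 128 ± 9.74 (adjusted p = 2.42e-07). HDS was 0.56 ± 0.13 higher on the log2 scale (adjusted p = 0.00806), and without ceh1 replicate 2 its adjusted p was 0.0626. The 1860 called genes were 1084 higher and 776 lower, with 235 and 230 changed at least 2-fold. Of genes higher in eds16 than in Col-0, 95 were also higher here, against 17.7 for independent calls, and of the lower genes 155, against 23.

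By list, 16 of 33 salicylic acid genes were lower and 4 higher in ceh1/eds16 than in ceh1 (list adjusted p = 6.12e-07, limma camera, or adjusted p = 0.0656 with an estimated correlation). The disrupted gene ICS1 is among the lower ones here too. Endoplasmic reticulum stress genes had 10 of 25 lower (12 adjusted over the list alone, 2.8e-08), which held with an estimated correlation, although BIP3 read 2036 ± 95.6 and 1656 ± 96.2 (adjusted p = 0.268). Jasmonate had 13 higher and 1 lower (16 and 1 adjusted over the list alone, 2.8e-08, or adjusted p = 0.339 with an estimated correlation). Rapid stress genes had 8 and 1 (14 and 1 adjusted over the list alone, 2.66e-05, or adjusted p = 0.369 with an estimated correlation). Camalexin had 4 and 0 (6 adjusted over the list alone, 0.00228, or adjusted p = 0.0656 with an estimated correlation), with PAD3 at 1177 ± 96.9 against 551 ± 93.8. Abscisic acid had 4 higher and 1 lower (6 and 1 adjusted over the list alone, 0.00228, or adjusted p = 0.361 with an estimated correlation). Lower lists were receptor kinases with 7 (8 lower and 1 higher adjusted over the list alone, 0.00276, or adjusted p = 0.414 with an estimated correlation) and cell wall expansion with 5 (0.00031, or adjusted p = 0.144 with an estimated correlation). Others were auxin with 1 (3 adjusted over the list alone, 0.0101, or adjusted p = 0.144 with an estimated correlation) and the cell cycle with 2 (0.00464, or adjusted p = 0.369 with an estimated correlation). The count was 1017 and 1118 without ceh1 replicates 1 and 2 and 3248 without ceh1/eds16 replicate 3. Rapid stress genes had 2 higher without ceh1 replicate 1 or 2, 4 and 5 without ceh1/eds16 replicates 1 and 2, and 13 without ceh1 replicate 3. Auxin had 5 lower without ceh1/eds16 replicate 3, and 2 without Col-0 replicate 3 or ceh1 replicate 3. The cell cycle had 0 lower without ceh1 replicate 1 or 2 or ceh1/eds16 replicate 1, and 1 without ceh1 replicate 3. Camalexin had 2 higher without ceh1 replicate 1, and cell wall expansion 3 lower without ceh1 replicate 1 or ceh1/eds16 replicate 1.

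The scale of the values matters for the direction of change. Scaling to equal library totals put the median log2 fold change of all genes at 0.24 in ceh1 against Col-0 (0.008 as deposited) and at 0.116 in ceh1/eds16 against eds16 (0.005 as deposited). The share of called genes that were higher went from 50.3% to 72% and from 52.2% to 64%. Quantile normalization moved it the other way, to 45.4% and 44.3%, and equal upper quartiles gave 51.7% and 44.3%. Equal library totals gave 35.9% higher for the difference of effects (63.3% as deposited) and 38.4% for ceh1/eds16 against ceh1 (58.3%), and 45.5% for eds16 against Col-0 (35.6%). Equal upper quartiles gave 48% for eds16 against Col-0 and 44.5% for the difference, and quantile normalization gave 52.1% for the difference. Gene length also ran through the data. Across genes, the fold change correlated with exon length at -0.37 in ceh1 against Col-0 and -0.36 in eds16 against Col-0 (Spearman). The correlation was 0.38 for the difference. Without Col-0 libraries it was weaker, at -0.13 in ceh1/eds16 against eds16 and 0.19 in ceh1/eds16 against ceh1. A length bias between whole groups cannot be told apart from genotype.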

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

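The tests of the standing apart of ceh1/eds16 replicate 3, of the clock genes and of the defensin copies were chosen after the result was seen, while the regroupings of the libraries were written before the data were examined.

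The ceh1 effect was tested for a difference between the Col-0 and the eds16 background, and 891 genes passed (limma), 36 of them among the 135 genes named by the rule, 20 positive and 16 negative. In the negative group, with a smaller rise or a larger fall in the eds16 background, salicylic acid and defence genes were WRKY38 with -4.42 (log2), PR1 with -3.66, NIMIN1 with -3.14 and PCC1 with -2.07. Other genes that rose in ceh1 were ARD3 with -3.86, XTH10, a cell wall enzyme gene, with -3.01, the amino acid transporter gene LHT7 with -2.48, PCR1 with -1.68 and the phosphate starvation gene SPX1 with -1.10. XTH10 is the next locus after PR1 in the annotation, and whether reads running past PR1 contribute to it was not tested. LHT7 had an adjusted p of 0.062 without ceh1 replicate 1 and 0.0563 without ceh1 replicate 2, in a range of 0.000529 to 0.062 over its alternatives.

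Genes that fell further in the eds16 background were the wax genes CYP96A15 with -1.76 and CER4 with -1.63, the morning clock genes PRR9 with -1.55 and CCA1 with -1.26, and the antenna gene LHCB2.3 with -1.05. BBX18, a zinc finger gene of light signalling, read 139 ± 40 in ceh1 and 47.7 ± 9.13 in ceh1/eds16 (-2.13). PAP1, a regulator of anthocyanin synthesis, fell in ceh1/eds16 against eds16 and not in ceh1 against Col-0 (-1.44).

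In the positive group were AACT1 (AT5G61160) with 6.38 and the defensin genes PDF1.3 with 5.25, PDF1.2A with 5.15, PDF1.2c with 4.96 and PDF1.2b with 4.53. For PDF1.3 edgeR gave an adjusted p of 0.0896, in a range of 1.03e-07 to 0.0896 over its alternatives. JMJD5, a clock-linked demethylase gene, showed 4.002, with 22.6 ± 5.72 in ceh1 and 366 ± 116 in ceh1/eds16, and DIN11, a gene induced in the dark, 3.31, with 26.5 ± 6.4 and 372 ± 33.4. COR27 showed 3.12 and GRP7 1.29. Immune genes here were FMO1 with 3.64, PR5 with 1.87, PR2 with 1.82, the chitinase gene CHI (AT2G43570) with 1.80, RLP23 with 1.59 and ADR1 with 0.73. Stress genes were BIP3 with 1.22 and the glutathione transferase gene GSTF6 with 0.94. The triterpene synthase gene LUP1 with 1.23 and HMG1 with 0.87 had smaller falls in the eds16 background than in Col-0. SEN1 with 1.46 fell in ceh1 against Col-0 and was not called lower in ceh1/eds16 against eds16.

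For the 4 comparisons of 3 libraries with 3, the real split was 1 of 10 splits in each case, and 10 splits are too few for a share under 0.05. The real splits called 9183 genes for ceh1 against Col-0, 7736 for ceh1/eds16 against eds16, 841 for eds16 against Col-0 and 1860 for ceh1/eds16 against ceh1. The highest of the other splits called 0, 0, 1 and 1215 genes. The split with 1215 set ceh1 replicates 1 and 2 and ceh1/eds16 replicate 3 against ceh1 replicate 3 and ceh1/eds16 replicates 1 and 2, which points to a structure of the samples other than genotype. For the difference of effects, 4 of 100 regroupings of the residuals, the real one included, called at least 891 genes. That share is under 0.05, but it rests on few regroupings, and the highest other called 1307 genes. The regroupings treat all libraries as equally variable, while ceh1/eds16 replicate 3 stood apart from its group. They therefore exclude neither chance nor a structure of the samples other than genotype.

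That structure was seen most in ceh1/eds16 replicate 3, whose mean absolute deviation from its 2 group mates was 0.39 (log2). The leading component within groups (31.6% of the variance within groups) had gene weights that correlated with exon length at -0.69 across genes, which are not independent replicates, so a gene length bias of the libraries is a candidate source. The correlation with GC content of -0.18 leaves that bias open, and with both trends removed the deviation was 0.3 against at most 0.25 in the 9 libraries of the other groups, so it cannot be told apart whether length and GC are the whole cause. A later harvest of this library also stays open: its evening minus morning clock genes deviated by 0.69, against at most 0.3 in those 9 libraries, but its group mate replicate 1 deviated by more, -0.87, and its own clock value lay 0.14 from that of replicate 2. No biological explanation was tested, as no label sets this library apart.

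Evening clock genes minus morning clock genes (8 and 4 genes, difference of medians, log2) was 2.87 higher in ceh1/eds16 than in ceh1, which was itself 2.27 above Col-0, while eds16 was 0.56 above Col-0. One deviating library as the cause is argued against by a difference of 2.71 without ceh1/eds16 replicate 3. A later time of day at harvest of whole groups and a clock changed by the genotype cannot be told apart, since no label gives the hour and both predict this shift. The libraries stood at 3.17, 3.82 and 3.96 in ceh1/eds16 and 0.69, 0.61 and 1.04 in ceh1, without overlap. They spread more widely in ceh1/eds16 than in the other groups, whose largest range was 0.43.

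The defensin genes of the PDF1.2 family were high in ceh1/eds16 alone. Exchange of reads between the 4 near-identical copies cannot raise their sum. In the lowest ceh1/eds16 library the sum was 4.37 (log2) above the highest of the other 9 libraries. The mean of the ceh1/eds16 libraries without replicate 3, the highest, was 4.69 above that same library. Both outcomes were fixed once each of the 4 copies had been seen to rise in ceh1/eds16. They restate that rise and are no further evidence for it. With the length and GC trend removed the difference for PDF1.2A was 5.62. An effect of losing ICS1 in the ceh1 background thus stays as a hypothesis, found and tested on the same data, and a difference in harvest time of whole groups was not tested for these genes.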

How the results depend on the processing

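The removal of the length and GC trend, and the counts of list members and of differences along and against the ceh1 effect without single libraries, were chosen after the result was seen; all other alternatives were set before the data were examined. The counts for ceh1 against Col-0 and for ceh1/eds16 against eds16 stayed within 1.5 times 9183 and 7736 in every alternative run, with 7376 to 10326 and 6513 to 7987 when each library was left out. With the trend removed 6872 of the 9183 genes were called again in the same direction. Of 176 values of named genes 4 changed sign in some alternative and 25 lost their call in at least 1, and no list call turned to the opposite direction of its test, although the median of the flavonoid list in eds16 against Col-0 went from 0.152 to -0.056 (adjusted p = 0.979, limma camera) with the filter at 50. Other lists lost with that filter were ethylene in ceh1, floral markers in ceh1/eds16 against eds16, and oxidative stress and flavonoids in the difference of effects. The groups of a comparison alone give no difference of effects, 144 of the 176 named values passed the filter at 50, and DESeq2 left 710 genes without an adjusted p for the difference and for eds16 against Col-0.

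The difference of effects (891 genes) fell to 593 with no filter, where more genes are adjusted for, and to 554 without the variance trend, and was 1351 with the length and GC trend removed. The count for eds16 against Col-0 (841) was 512 without the trend and 1513 with only the groups of the comparison, and ceh1/eds16 against ceh1 (1860) gave 2798 with length and GC removed. Leaving out each library gave 347 to 3012 (without ceh1 replicate 1 and ceh1/eds16 replicate 3), 238 to 1780 (without Col-0 replicate 2 and ceh1/eds16 replicate 3) and 1017 to 3248 (without ceh1 replicate 1 and ceh1/eds16 replicate 3). The kept shares, 0.832 and 0.694, were 0.706 and 0.826 at equal library totals, so their order turned with the scaling, and with length and GC removed they were 0.922 and 0.84, the first near the 0.928 simulated with equal effects. The limma fry test lost jasmonate (difference of effects and eds16 against Col-0) and rapid stress (difference of effects). Quantile normalization lost oxidative stress there, and length and GC removal lost endoplasmic reticulum stress in eds16 against Col-0. Of the 70 list calls 9 remained with an estimated correlation. The fold changes of eds16 against Col-0 do not use ceh1/eds16 replicate 3. The rise of that count from 841 to 1780 without this library thus came through the spread, which the model estimates over all 12 libraries. Beyond this and the filter, the cause was not tested.

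The replicate numbers do not pair the libraries: 18 correlations between libraries of the same number ran from -0.45 to 0.12, and 4 of 12 libraries matched best with their own number. With the number as a block, 566 genes had a different effect and 538 were called for eds16 against Col-0, no other count moved by over 1.5 times, and 2 of the 176 named values, TGG1 and MPK6 in ceh1 against Col-0, lost their call.

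HDS in eds16 against Col-0, -0.03 (log2), was 0.019 at equal upper quartiles and 0.113 with length and GC removed, and -0.087 to 0.026 when libraries were left out (without eds16 replicates 1 and 2), with adjusted p (limma) of 0.537 to 1. PR5 in ceh1/eds16 against ceh1 ranged from -0.249 to 0.097 (without ceh1/eds16 replicates 3 and 1). In ceh1 against Col-0, HSP101 went from -0.50 to 0.047 with length and GC removed, and TGG1 from -0.48 to 0.479 with quantile normalization; the cause was not tested. Depth limits what can be said of genes with few reads, as 15313 of 33602 genes were under the mean of 10 and were not tested.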

Other observations

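The tests in this part are those of the report, and the genes other than PAP1, VSP2, FLC, SEP3 and AG were chosen after their values were seen. In eds16, 4 of 14 measured flavonoid and anthocyanin genes were higher than in Col-0, and the list call was lost with an estimated correlation (adjusted p = 0.217, limma camera) and with a filter at 50 (adjusted p = 0.979), which leaves these 4 genes out. The 4 were PAP1, DFR, LDOX and TT19. PAP1, a regulator of the pathway, read 20.7 ± 2.97 in Col-0, 32.8 ± 9.26 in ceh1, 57.9 ± 5.53 in eds16 and 32.5 ± 6.39 in ceh1/eds16 (eds16 against Col-0 1.44, adjusted p = 0.00264, limma). DFR, of a late step, read 27.8 ± 12.9, 31.9 ± 1.05, 89.2 ± 22.4 and 34.7 ± 5.67 (1.71, adjusted p = 0.00269). LDOX read 36.3 ± 8.77, 26.5 ± 2.53, 94.2 ± 20.7 and 25.7 ± 0.745 (1.35, adjusted p = 0.00258), and the transport gene TT19 22.7 ± 5.72, 33.7 ± 8.89, 73.6 ± 29.9 and 31.3 ± 10.2 (1.62, adjusted p = 0.00805). The ceh1 effect differed between the backgrounds for PAP1 by -1.44 (adjusted p = 0.0238), DFR by -1.61 (adjusted p = 0.0323), LDOX by -1.39 (adjusted p = 0.0189) and TT19 by -1.74 (adjusted p = 0.0354).

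VSP1 and VSP2, storage protein genes induced by jasmonate, had their highest means in eds16, with VSP1 at 403 ± 92.6 in Col-0, 435 ± 73.5 in ceh1, 1150 ± 535 in eds16 and 533 ± 51.2 in ceh1/eds16, and both fell in ceh1/eds16 against eds16 (VSP1 -0.995 and VSP2 -1.32, adjusted p = 0.00501 and 0.00354, limma). ORA59, a regulator of defensin genes, read 15.6 ± 3.51, 40.4 ± 5.8, 9.66 ± 5.4 and 195 ± 68.9. AOS, of jasmonate synthesis, fell in ceh1 against Col-0 (-0.86, adjusted p = 6.01e-05) and read 1379 ± 123, 759 ± 57, 1486 ± 118 and 1750 ± 348. HPL1, which uses the same fatty acid peroxides, read 66.2 ± 13.4, 61 ± 8.15, 85.7 ± 12.2 and 222 ± 17.1 and had a positive difference of effects of 1.47 (adjusted p = 0.00315).

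FLC, a repressor of flowering, rose from 17.5 ± 7.2 in Col-0 to 89.8 ± 16.5 in ceh1 (adjusted p = 5.21e-06, limma) and from 32 ± 11.9 in eds16 to 77.5 ± 15.6 in ceh1/eds16 (adjusted p = 0.00162). SEP3, a floral organ gene, fell from 52 ± 10.9 to 14.7 ± 8.39 (adjusted p = 0.000423) and from 102 ± 28.6 to 15.6 ± 0.843 (adjusted p = 2.38e-05). AG, another, fell from 15.4 ± 5.24 to 2.81 ± 1.03 and from 27.6 ± 0.55 to 1.84 ± 1.78, both at few reads. The floral list did not pass in ceh1 against Col-0 (adjusted p = 0.0898, limma camera), and in the eds16 background it was lost with an estimated correlation (adjusted p = 0.189) and with a filter at 50 (adjusted p = 0.503). The mitotic cyclin gene CYCB1-2 read 195 ± 19, 289 ± 38.2, 314 ± 67.4 and 260 ± 18.3 in the order Col-0, ceh1, eds16 and ceh1/eds16 (difference of effects -0.81, adjusted p = 0.0449), and CYCA1-1 132 ± 25, 199 ± 14.6, 196 ± 7.67 and 154 ± 12.1 (-0.96, adjusted p = 0.0151).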
